A study of Homo sapiens with 222 samples.

How the data were processed

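Whole-blood RNA was hybridised to Illumina expression bead arrays. Per the labels' protocols, blood was drawn into PAXgene tubes, globin transcripts were removed with GLOBINclear and the RNA was amplified and labelled with biotin. Groups were taken from the sample titles: 190 Sjögren and 32 control samples, treated as separate donors; where 2 samples came from 1 donor, p-values would measure only the spread between samples. The sources used here give a case and control design. Age, sex and treatment were not used here.

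The deposited signal table holds a linear signal intensity for each of 48803 probes on every array, with values below 0, which shows that background had been subtracted before deposit; it is not normalized, per the file headers. Of these intensities 28.9% were below 0. The deposited table also gives a detection p-value per probe and array. The authors' processed table holds log2 values for 15063 of the probes, and the submitters' processing notes name RMA, with the version not given in the sources used here. Each of its columns matched best the signals of its own array. The column medians ran from 6.54 to 6.58. Correlations with the log2 signals of the same array ran from 0.977 to 0.992, so the scale is log2 and the values were not centred by gene; the adjustment that made its chip sets alike is not stated.

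Signals were corrected with normexp, using detection p-values to infer the negative controls, then quantile normalized and log2 transformed with an offset of 16 (neqc in limma 3.58.1 under R 4.3.3). Probes were tested when detection p was under 0.01 on at least 32 arrays, which left 15631. The 7 named probes of XIST, TSIX and Y-linked genes were left out. The chip set explained 93.1% of the first principal component of the normalized values, which held 35.6% of the variance, and 1.14% of the first component of the authors' table. The mean signal of tested probes was 399.6 on Sjögren arrays of the first set and 1127 on those of the second.

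The main model had the group and the chip set as fixed terms and the chip as a random block (duplicateCorrelation with statmod 1.5.0, consensus correlation 0.184), followed by limma's empirical Bayes test and Benjamini-Hochberg adjustment over the tested probes at 0.05. Of 55 chips 16 held both groups. Symbols came from a table of platform annotation that names 12520 of the probes of the authors' table, 12518 with 1 symbol and 2 with several, updated through gene identifiers of the GRCh38.p14 RefSeq gene table, where 12513 matched. Probes outside it are unnamed here, 819 of those that passed among them. A gene was read from its brightest tested probe. Of 1763 genes with several tested probes, 2 had probes called in opposite directions.

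The 26 gene lists, the tests and the genes to name were fixed before the data were examined. They covered type I interferon, interferon-gamma, disease locus, MHC class I and class II, neutrophil, immature granulocyte, monocyte, T cell, NK and cytotoxic, B cell, plasma cell, plasmacytoid dendritic cell, platelet, erythroid, globin, eosinophil and basophil, inflammatory cytokine, immediate early, Toll-like receptor and inflammasome, costimulation, proliferation, ribosomal protein, oxidative phosphorylation, proteasome and mitochondrial ribosomal protein genes. Named genes were the 12 largest rises and 12 largest falls past the threshold, the 4 members of each list with the smallest p, every measured locus gene and the 15 interferon genes with the largest difference; not every gene under that rule is named. Lists were tested with camera on the moderated statistics with a preset correlation of 0.01 and with a correlation estimated from residuals. List scores were compared by two-sided permutation of labels within chip sets, 100000 times, and adjusted over the 26 lists. Alternatives used 20000 permutations.

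The share of Sjögren arrays above the highest control carries an exact binomial interval. Mixtures of normal components with equal variance were fitted to the Sjögren scores with mclust 6.1.1. The use of 2 parts split at the fitted boundary of 1.76 was chosen after the data were seen. Removing the chip set aligned the sets mostly on their Sjögren arrays, because the second set held 2 controls.

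On simulated arrays with 15631 probes, the same chips and 50 probes changed per size, the comparison of Sjögren with control recovered 52% of changes of 0.25 on the log2 scale and 100% of changes of 0.5, 1 and 2, and called 7 of 15431 unchanged probes. Simulated unchanged scores, drawn without any likeness of arrays within a chip, fell under an unadjusted p of 0.05 in 4.40% of cases. They cannot show how chips affect the score test. The simulated probes varied independently of each other, so the count of unchanged probes called leaves out correlation between genes. No arrays held identical values. Alternatives covered background, normalization, the authors' values, the probe filter, batch terms, array quality, blood cell scores as covariates, and the shared replicate number as a block.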

Results

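Whole-blood transcript levels were measured on Illumina bead arrays, 1 per sample: 190 from people with Sjögren's syndrome, an autoimmune disease of the salivary and tear glands, and 32 from controls. The arrays lay on 55 chips of 2 chip sets. The first set held 95 Sjögren and 30 control arrays, and the second held 95 Sjögren and 2 control arrays. Each array detected between 10853 and 15026 of 48803 probes, with a median of 13690. Sjögren arrays detected 320.03 more probes than controls on average with the chip set removed (permutation p = 0.0403, two-sided). The number of arrays limits the precision.

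The comparison of Sjögren with control blood asked which transcripts differ between the groups. Transcripts induced by type I interferon rose most. IFI27, an interferon-inducible mitochondrial protein gene, was 8.69-fold higher (log2 difference 3.12, SE 0.58, adjusted p = 2.54e-05). IFI44L was 5.88-fold higher (log2 difference 2.56, SE 0.41, adjusted p = 8.87e-07), and RSAD2, which encodes the antiviral enzyme viperin, was 5.20-fold higher (log2 difference 2.38, SE 0.40). The other 9 of the 12 largest rises were IFI44 at 4.14-fold, OTOF at 3.99-fold, ISG15 at 3.47-fold, EPSTI1 at 3.37-fold, LY6E at 3.30-fold, IFIT1 at 3.29-fold, IFIT3 at 2.79-fold, CMPK2 at 2.74-fold and IFI6 at 2.63-fold. All 12 belonged to the list of type I interferon genes fixed before the data were examined. OTOF was dim in controls, with a mean log2 signal of 4.81. With the chip set removed, IFI27 lay above the control mean in 156 of 190 Sjögren arrays, IFI44L in 167 and IFI6 in 149. That removal aligned the sets mostly on their Sjögren arrays, so these counts say little about the second set on its own. Against the 2 controls of the second set, plain differences of mean log2 signal were 0.61 for IFI27, 0.45 for IFI44L and -0.26 for IFI6.

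The falls were smaller than the rises. LRRN3, a leucine-rich repeat gene of naive T cells, fell by 1.06 on the log2 scale (SE 0.24, adjusted p = 7.46e-04), and its second probe fell by 0.69. RBPMS2, an RNA-binding protein gene, fell by 1.03 (SE 0.15, adjusted p = 2.20e-07). With the chip set removed it lay below the control mean in 175 of 190 Sjögren arrays. Its plain difference of mean log2 signal was -1.05 on the first chip set and -0.11 on the second, with 2 controls. CD248, which encodes the surface protein endosialin, fell by 0.96 (SE 0.16, adjusted p = 2.60e-06). The log2 differences of the next falls were -0.87 for ELAPOR1, -0.84 for MYOM2, -0.79 for SERPINE2, -0.78 for FEZ1, -0.76 for LRRC26, -0.75 for ASF1B, -0.74 for TGM3, -0.72 for SPRYD3 and -0.71 for ALPL.

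**Figure D1:**
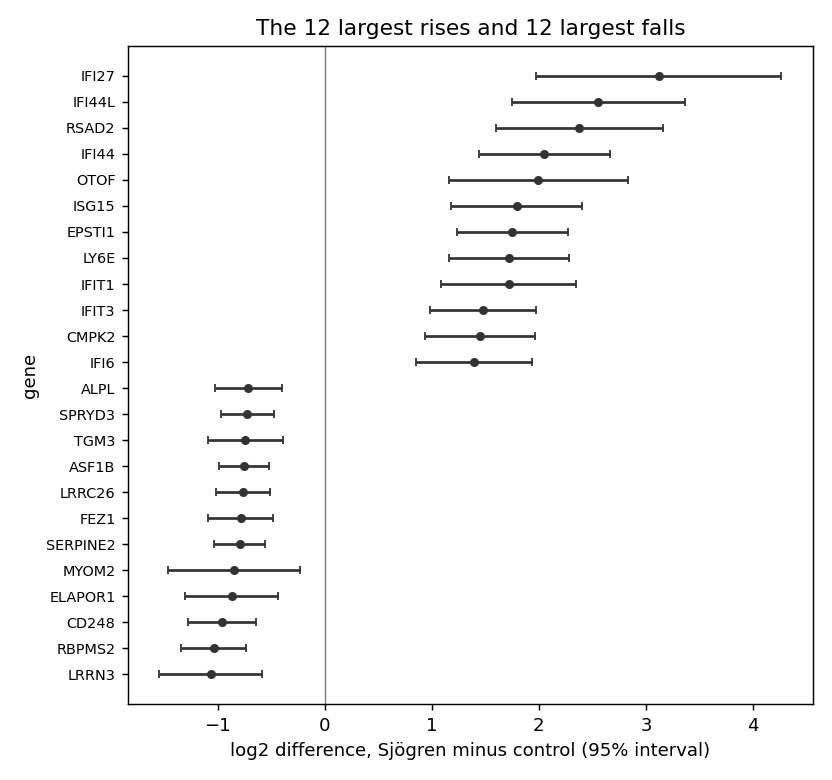
Log2 difference of Sjögren minus control (x axis) for the 12 genes with the largest rise and the 12 with the largest fall (y axis) among those past adjusted p 0.05; points are limma estimates and bars their 95% intervals. The rises run from 1.39 for IFI6 to 3.12 for IFI27 and the falls from -0.71 for ALPL to -1.06 for LRRN3.

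Of 8617 named genes, 1631 passed limma's test at adjusted p 0.05, 800 higher and 831 lower in Sjögren blood, with a median absolute log2 difference of 0.24 among them. A rise of 1.5-fold or more was met by 65 genes and a fall of that size by 26. At the 2-fold level there were 27 higher and 2 lower genes. Over all 15631 tested probes 2858 passed, 1424 higher and 1434 lower. With median scaling of the arrays in place of quantile normalization 2517 passed, 820 higher and 1697 lower, so the even split depended on the scaling. The first chip set alone gave 2882 probes, and the second, with 2 controls, gave 0 in limma at adjusted p 0.05 and 1259 at an unadjusted p under 0.05. With every chip as its own term 1498 probes passed.

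The type I interferon list moved as a group. Of its 37 measured genes 36 were higher in Sjögren blood and 0 lower, and 37 were higher when adjusted over the list alone, with a median log2 difference of 1.23. XAF1 (log2 difference 1.36), IFITM3 (1.29) and SPATS2L (1.29) followed the genes named above, and the RNA sensor IFIH1 (0.98) and the kinase EIF2AK2 (1.07) were among the members with the smallest p. The list passed camera's test with a preset correlation (adjusted p = 3.81e-42) and missed it with adjusted p = 0.0891 with an estimated correlation. Among 18 interferon-gamma genes 13 were higher and 0 lower, with 15 higher when adjusted over the list alone. The guanylate-binding proteins GBP1 (log2 difference 1.01, SE 0.16), GBP5 (0.90) and GBP4 (0.66) and the chemokine CXCL10 (1.10, SE 0.20) led them. That list had adjusted p = 6.04e-12 with the preset and adjusted p = 0.167 with an estimated correlation.

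Each of the 26 gene lists was also reduced to a score per array, and group labels were permuted within chip sets. The score was the mean over the list's genes, each in SDs of that gene among controls. A unit is therefore not 1 SD of the control scores, which was 0.817 for type I interferon and 0.269 for locus genes. In that test 12 lists passed an adjusted p of 0.05, 9 higher and 3 lower. With the preset correlation camera called 17 lists, and with an estimated correlation it called 0; no list below held its camera call with the estimate, and the permutation p values of the scores are the ones given first. Arrays of 1 chip resembled each other (median residual correlation 0.148, against -0.0108 between chips), and 16 of 55 chips held both groups. With every chip as its own term and labels permuted within chips, 6 of the 12 lists passed: type I interferon, interferon-gamma, inflammatory cytokine, MHC class II, locus and platelet genes. The other 6 had adjusted permutation p values of 0.0520 for MHC class I, 0.111 for monocyte and for plasmacytoid dendritic cell, 0.121 for costimulation and 0.419 for neutrophil and for proliferation genes. In that fit camera with the preset correlation gave adjusted p = 0.168 for neutrophil, 0.0840 for proliferation, 0.0775 for costimulation and 0.0528 for locus genes. The other 6 lists had score differences in that fit of 0.416 for MHC class I, 0.341 for monocyte and 0.305 for costimulation genes. The differences were -0.302 for plasmacytoid dendritic cell, -0.224 for neutrophil and 0.212 for proliferation genes. Main values, in that order, were 0.320, 0.319, 0.282, -0.272, -0.403 and 0.308. With median scaling of the arrays 6 of the 12 lists passed the score test: both interferon lists and inflammatory cytokine, neutrophil, plasmacytoid dendritic cell and platelet genes. The remaining scores there were 0.0797 for MHC class I (adjusted permutation p = 0.556), 0.225 for MHC class II (0.155), 0.138 for locus (0.155), 0.143 for monocyte (0.289), 0.206 for costimulation (0.0807) and 0.167 for proliferation genes (0.210).

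**Figure D2:**
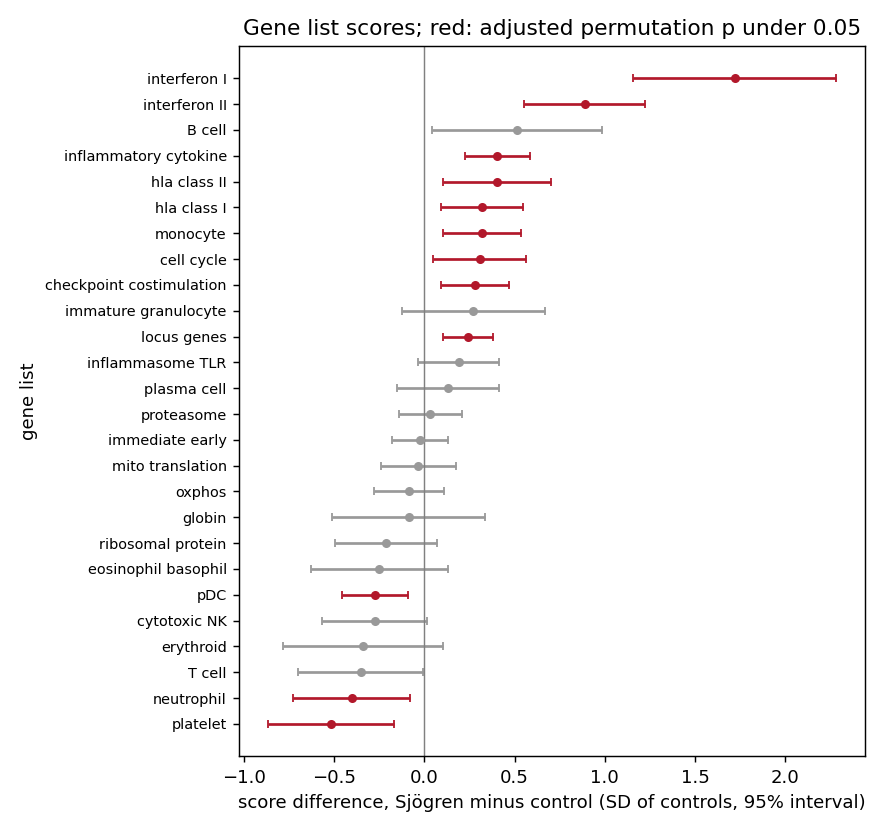
Difference of Sjögren minus control in the score of each of the 26 gene lists (x axis, mean over genes in each gene's control SD, with lists on the y axis), with 95% intervals. Red points passed an adjusted permutation p of 0.05. The interferon lists stand highest at 1.72 and 0.889, and the platelet list lowest at -0.519.

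The scores of 3 inflammatory and antigen-presentation lists were higher, while most of their genes did not pass. The score of inflammatory cytokines and NF-kB targets rose by 0.405 (adjusted permutation p = 5.20e-04; camera adjusted p = 0.0150 preset and adjusted p = 0.344 with an estimated correlation). Of its 15 genes 5 were higher and 0 lower, the same counts adjusted over the list alone, led by the monocyte chemokine CCL2 (log2 difference 0.70, SE 0.15) and TNFAIP6 (0.66), with NFKBIZ at 0.23. CCL2 was dim in controls, with a mean log2 signal of 4.75. With probes detected on at least 111 arrays the score difference of this list was 0.293 (adjusted permutation p = 0.00607). MHC class I and processing genes scored 0.320 higher (adjusted permutation p = 0.0221; camera adjusted p = 0.00889 preset and adjusted p = 0.399 with an estimated correlation), with 5 of 17 higher and 0 lower, also when adjusted over the list alone: the peptide transporter TAP1 (log2 difference 0.42), PSMB8 (0.25), PSME1 (0.22) and NLRC5 (0.32) were among them. MHC class II genes scored 0.402 higher (adjusted permutation p = 0.0131; camera adjusted p = 0.00889 preset and adjusted p = 0.399 with an estimated correlation), with 3 of 10 higher and 0 lower, also when adjusted over the list alone: HLA-DRA (log2 difference 0.34), its chaperone CD74 (0.29) and HLA-DRB3 (0.36), uncertain because HLA-DRB genes are near-identical. With blood cell scores, monocyte and B cell ones included, as covariates the class II score difference was -0.0434 (adjusted permutation p = 0.649), with 0 genes higher and 1 lower. On the second chip set, with 2 controls, it was -0.0902.

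Costimulation and TNF family genes scored 0.282 higher (adjusted permutation p = 0.0131; camera adjusted p = 0.0459 preset and adjusted p = 0.399 with an estimated correlation). Of 18 genes 3 were higher and 0 lower, also when adjusted over the list alone: TNFSF10, the death ligand TRAIL (log2 difference 0.48), TNFSF13B, the B cell survival factor BAFF (0.41), and the inhibitory receptor TIGIT (0.35). Proliferation genes scored 0.308 higher (adjusted permutation p = 0.0250; camera adjusted p = 0.00889 preset and adjusted p = 0.560 with an estimated correlation), with 5 of 19 higher and 0 lower, and 5 higher and 1 lower when adjusted over the list alone. TOP2A (log2 difference 0.44, dim in controls with a mean log2 signal of 4.79), TYMS (0.37), NUSAP1 (0.31) and CCNA2 (0.25) led that list. With median scaling 1 of its genes was higher, and 0 when adjusted over the list alone; with probes detected on at least 111 arrays 2 of 15 were higher and the score was 0.221 (adjusted permutation p = 0.102). Its score difference was 0.710 over both chip sets without control 14 (adjusted permutation p = 0.00162), 0.256 with the number of detected probes as a covariate (0.0623) and 0.158 with blood cell scores as covariates (0.222). On the second chip set it was -1.40 with both controls and 0.488 without control 14. Genes at or near loci tied to Sjögren's syndrome, recalled from the study these samples belong to and so not independent evidence, scored 0.243 higher (adjusted permutation p = 0.00903; camera adjusted p = 0.0402 preset and adjusted p = 0.167 with an estimated correlation). Of 12 measured genes 5 were higher and 1 lower, and 5 higher and 2 lower when adjusted over the list alone. HLA-DRA, PHIP (log2 difference 0.23), TNFAIP3 (0.23), PRDM1 (0.24) and DGKQ (0.31) were higher and TNIP1 (-0.30) lower, while FCGR2A (-0.18), CXCR5 (0.18), TNPO3 (0.03), PTTG1 (0.04), BLK (0.04) and STAT4 (0.01) did not pass.

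Marker genes of blood cell types moved in both directions. Platelet genes had a score difference of -0.519 (adjusted permutation p = 0.0131; camera adjusted p = 9.70e-06 preset and adjusted p = 0.399 with an estimated correlation). Of 19 platelet genes 8 fell and 0 rose, and 12 fell when adjusted over the list alone: TREML1 (log2 difference -0.65, SE 0.15), the chemokine genes PPBP (-0.67, SE 0.19) and CXCL5 (-0.40), and the adhesion molecule ESAM (-0.47). Neutrophil genes had a score difference of -0.403 (adjusted permutation p = 0.0250; camera adjusted p = 0.0145 preset and adjusted p = 0.560 with an estimated correlation), with 4 of 19 lower and 0 higher, also when adjusted over the list alone: ALPL, CMTM2 (log2 difference -0.44) and the interleukin-8 receptors CXCR2 (-0.31) and CXCR1 (-0.28). With the number of detected probes as a covariate the neutrophil score difference was -0.250 (adjusted permutation p = 0.148), and 2 genes were lower (camera adjusted p = 0.338 preset); with the median over the genes in the score it was -0.344 (adjusted permutation p = 0.0679). On the second chip set it was 0.323 with both controls and -0.132 without control 14. Plasmacytoid dendritic cell genes had a score difference of -0.272 (adjusted permutation p = 0.0131; camera adjusted p = 0.0816 preset and adjusted p = 0.399 with an estimated correlation). Of 12 such genes 4 were lower, among them LRRC26, CLIC3 (log2 difference -0.59) and PTCRA (-0.45), and 1, the RNA receptor TLR7, was higher (0.38). Adjusted over the list alone 5 were lower and 1 higher. The list median was -0.098 (log2) and 7 genes were not called, so the score does not show a fall of the list as a whole.

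Monocyte genes scored 0.319 higher (adjusted permutation p = 0.0131; camera adjusted p = 0.0134 preset and adjusted p = 0.399 with an estimated correlation), with MS4A7 (log2 difference 0.34), CX3CR1 (0.32) and FGL2 (0.19) higher among 14, 0 lower, and 5 higher when adjusted over the list alone. On the second chip set that score difference was -0.197. B cell genes had a score difference of 0.513 that missed the threshold (adjusted permutation p = 0.0734; camera adjusted p = 0.00889 preset and adjusted p = 0.560 with an estimated correlation). Its 3 higher genes among 15, also when adjusted over the list alone, were CD22 (log2 difference 0.42), TCL1A (0.62) and EBF1 (0.36). The B cell score passed at 0.589 with normexp fitted without negative controls (adjusted permutation p = 0.0417) and at 0.556 with array weights (0.0422). T cell genes had a score difference of -0.354 (adjusted permutation p = 0.0734; camera adjusted p = 0.0121 preset and adjusted p = 0.560 with an estimated correlation), with CD8B (log2 difference -0.48) the 1 lower gene of 22, also when adjusted over the list alone. The T cell score passed at -0.478 with median scaling (adjusted permutation p = 0.0156), at -0.542 with the number of detected probes as a covariate (0.00520), at -0.316 with array weights (0.0457) and at -0.403 without control 13 (0.0432). NK and cytotoxic genes had a score difference of -0.275 (adjusted permutation p = 0.116; camera adjusted p = 0.0121 preset and adjusted p = 0.560 with an estimated correlation). Of those 24 genes KLRB1 (log2 difference -0.52), CD160 (-0.43) and the activating receptor NCR3 (-0.42) were lower, 3 also when adjusted over the list alone.

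Other cell lists did not pass the score test in the main setting. Erythroid genes had a score difference of -0.340 (adjusted permutation p = 0.211; camera adjusted p = 0.0134 preset and adjusted p = 0.667 with an estimated correlation), with 2 of 24 lower, HEMGN (log2 difference -0.56) and STRADB (-0.44), and 0 when adjusted over the list alone. With array weights the erythroid score was -0.493 (adjusted permutation p = 0.0477). On the second chip set it was 0.768, and the list median was 0.76 (log2) with both controls (camera adjusted p = 3.02e-05 preset) and -0.077 without control 14. Eosinophil, basophil and mast cell genes had a score difference of -0.249 (adjusted permutation p = 0.211), with FCER1A (log2 difference -0.69) and CPA3 (-0.64) the 2 lower genes of 11, also when adjusted over the list alone. Plasma cell genes had a score difference of 0.132 (adjusted permutation p = 0.421), with PRDM1 and CD38 (log2 difference 0.37) higher and ITM2C (-0.24) lower among 12, 2 and 1 also when adjusted over the list alone. Granule genes of immature neutrophils had a score difference of 0.271 (adjusted permutation p = 0.262) and 0 of 15 genes called, also when adjusted over the list alone; DEFA4 had a log2 difference of 0.50 (SE 0.28). Globin genes, some of them targets of globin removal, had a score difference of -0.0863 (adjusted permutation p = 0.608) and 0 of 8 called, also when adjusted over the list alone; HBB had a log2 difference of -0.03. With median scaling the globin score difference was -0.400 (adjusted permutation p = 0.0550).

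Among housekeeping and stress lists no score passed in the main setting. Ribosomal protein genes had a score difference of -0.211 (adjusted permutation p = 0.211; camera adjusted p = 0.00123 preset and adjusted p = 0.601 with an estimated correlation), with 4 of 70 lower, also when adjusted over the list alone: RPL4 (log2 difference -0.37), RPL21 (-0.45), RPS4X (-0.27) and RPL32 (-0.20), genes with many near-identical pseudogene copies. With median scaling that score was -0.391 (adjusted permutation p = 0.0156), with 29 of 70 genes lower and 0 higher, and 36 lower and 1 higher when adjusted over the list alone. Toll-like receptor, inflammasome and complement genes had a score difference of 0.191 (adjusted permutation p = 0.119; camera adjusted p = 0.0450 preset and adjusted p = 0.560 with an estimated correlation), with 5 of 23 higher and 6 when adjusted over the list alone, TLR7, CASP1 (log2 difference 0.29), C2 (0.31) and IRAK1 (0.14) among them. With the number of detected probes as a covariate that score was 0.286 (adjusted permutation p = 0.0196). Immediate early genes had a score difference of -0.0251 (adjusted permutation p = 0.761): ATF3 (log2 difference 0.65) and KLF4 (0.47) were higher and 3 of 22 genes lower, with PPP1R15A (-0.26) and FOSL2 (-0.23) among them, and 4 were higher and 4 lower when adjusted over the list alone. The median of that list was negative and its mean and camera direction positive. Score differences were -0.0834 for 63 oxidative phosphorylation genes (adjusted permutation p = 0.520), 0.0335 for 32 proteasome genes (0.761) and -0.0334 for 71 mitochondrial ribosomal protein genes (0.761). Called genes numbered 3 higher and 1 lower, 1 higher and 1 lower, and 4 higher and 3 lower in those 3 lists, and 1 higher and 0 lower, 1 higher and 1 lower, and 0 higher and 0 lower when adjusted over the list alone.

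The interferon score asked how far donors differed in the type I interferon genes. It was 1.72 higher in Sjögren arrays (SD 1.49, n = 190) than in controls (SD 0.817, n = 32), with a 95% interval of 1.16 to 2.28 and a permutation p of 1e-05, the smallest that 100000 permutations can give. With blood cell scores as covariates it was 1.05 (adjusted permutation p = 9.50e-04), and the interferon-gamma score difference was 0.571 in place of 0.889. On the first chip set the difference was 1.81. On the second, with 2 controls, it was 0.639 (exact permutation p = 0.596 over 4656 splits). The SD of Sjögren arrays exceeded that of controls by 0.675, and by 0.697 on the first chip set alone. The spread was tested by permuting labels on absolute deviations from group medians. That gave permutation p = 1e-05, the smallest possible, and permutation p = 2e-05 on the first chip set alone. Labels were permuted within chip sets and not within chips, so these p values leave out the likeness of arrays within a chip. Above the highest control of their own set lay 39 of the 95 Sjögren arrays of the first set (41.1%, exact 95% interval 31.1 to 51.6). That limit, 2.62, was set by 1 control; the next control of the set lay at 1.59, and 56 Sjögren arrays (58.9%, exact 95% interval 48.4 to 68.9) lay above it. On the second set 51 of 95 (53.7%) lay above the higher of the 2 controls.

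**Figure D3:**
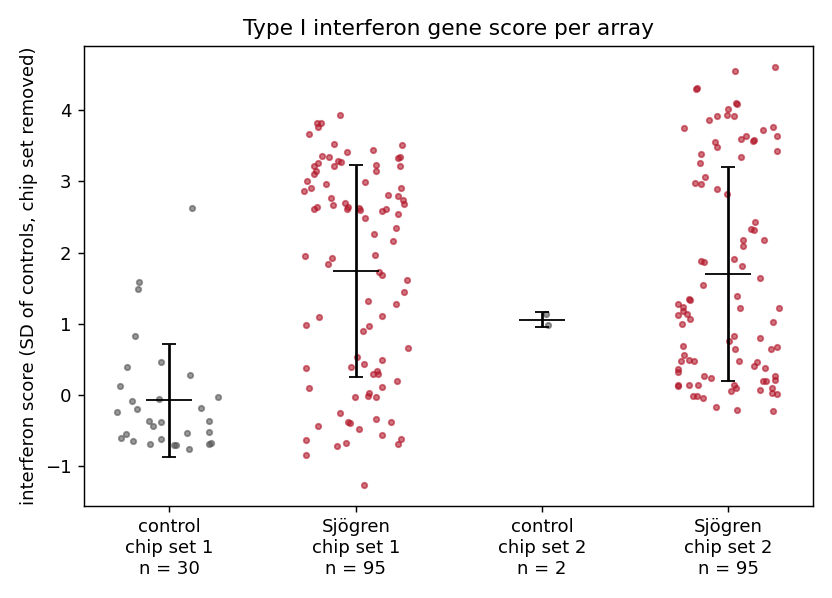
Type I interferon score of each array (y axis, mean over genes in each gene's control SD, with the chip set removed) by group and chip set (x axis). Each point is 1 array, and bars show the mean and SD. Sjögren scores lie on either side of the fitted boundary of 1.76 on both sets, and the control arrays of the first set lie at or below 2.62.

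Sjögren scores were better described by a mixture of 2 normal components than by 1, by 50.7 in the Bayesian information criterion, with means of 0.435 and 3.08 and a common SD of 0.686. The boundary of 1.76 put 97 arrays in a lower and 93 in an upper part, which adjoined: 24 of the 190 arrays lay within 0.5 of it. Each chip set fitted alone also favoured 2 components, by 35.2 and 37.5. Component means were 0.0958 and 2.83 on the first set and 0.687 and 3.49 on the second. The first set's boundary of 1.41 had 38 arrays below and 57 above, the second set's boundary of 2.17 had 61 and 34. The pooled boundary and counts therefore depend on how the sets were aligned. The 32 controls also favoured 2 components over 1, by 6.58. No correlation over all Sjögren arrays was computed, and the interferon score was related to 25 other list scores within each part, 50 relations in all, with members shared with the interferon list removed and chip set means removed. Interferon-gamma genes rose with the interferon score in the lower part (Pearson r = 0.636, Spearman rho = 0.689, n = 97) and the upper part (r = 0.465, rho = 0.456, n = 93). MHC class I genes did so too, at r = 0.503 and rho = 0.508 in the lower part and r = 0.427 and rho = 0.432 in the upper, as did inflammatory cytokine genes, at r = 0.402 and rho = 0.403 and at r = 0.449 and rho = 0.433. Raw permutation p values of these 6 Pearson correlations ran from 1e-05, the smallest possible, to 4e-05, and adjusted ones from 7.14e-05 to 2e-04.

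In the upper part the interferon score also varied with Toll-like receptor, inflammasome and complement genes (r = 0.519, rho = 0.503, permutation p = 1e-05 and adjusted p = 7.14e-05), immediate early genes (r = 0.464, rho = 0.381, permutation p = 1e-05), monocyte genes (r = 0.417, rho = 0.424, permutation p = 1e-05) and neutrophil genes (r = 0.346, rho = 0.280, permutation p = 7.4e-04, adjusted p = 0.00308). It varied inversely with ribosomal protein genes (r = -0.480, rho = -0.457, permutation p = 1e-05) and T cell genes (r = -0.374, rho = -0.324, permutation p = 2.3e-04, adjusted p = 0.00105). Oxidative phosphorylation genes (r = -0.238, rho = -0.167, adjusted p = 0.0409) and mitochondrial ribosomal protein genes (r = -0.250, rho = -0.188, adjusted p = 0.0392) passed for Pearson's r alone. Without the 2 arrays farthest from the median those 2 relations no longer held (r = -0.193 and r = -0.191), and the other 12 did. Given the neutrophil and T cell scores, partial correlations in the upper part were 0.277 for monocyte, 0.328 for immediate early and -0.337 for ribosomal protein genes (adjusted p = 0.0226, 0.00598 and 0.00307), and the oxidative phosphorylation and mitochondrial ribosomal protein relations were -0.132 and -0.0670 (adjusted p = 0.328 and 0.612). Within chip sets, the relation with interferon-gamma genes was r = 0.621 and 0.684 in the lower part and 0.355 and 0.555 in the upper, on the first and the second set, and the relation with ribosomal protein genes in the upper part was r = -0.496 and -0.511. The relation with T cell genes in the upper part was r = -0.229 on the first set (adjusted p = 0.320) and -0.478 on the second (0.00800), and with the boundary fitted within each chip set it was -0.165 (0.277). For neutrophil genes it was r = 0.379 and 0.335 on the 2 sets (adjusted p = 0.0283 and 0.122), and 0.241 with boundaries fitted within sets (0.0725). MHC class I genes in the upper part had r = 0.333 (adjusted p = 0.0546) and 0.534 on the 2 sets. With chip means removed, the relations with oxidative phosphorylation and mitochondrial ribosomal protein genes were 0.0461 and 0.0147. In the lower part r was 0.119 for Toll-like receptor, 0.0437 for immediate early, 0.142 for monocyte and 0.0493 for neutrophil genes. There it was -0.167 for ribosomal protein and -0.208 for T cell genes. None of these lower-part relations passed, and no test compared the 2 parts.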

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

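Settings added only after the data were seen were those with the interferon score or the number of detected probes as a covariate, chip means removed, the second chip set alone for relations, the boundary fitted within each chip set, and the 2 controls of the second chip set, 13 and 14, left out in turn. The interferon score difference stayed past its threshold, between 1.05 with blood cell scores as covariates and 1.81, in all settings run except the second chip set alone, where it was 0.639 with 2 controls, 0.715 without control 13 and 0.564 without control 14. The difference in spread stayed between 0.543 and 0.697 in its settings, none of which had a chip term. The number of relations called stayed between 12 and 16 against 14. Called probes numbered 2858 and moved to 8375 with neither chip set nor chip in the model, 1498 with every chip as its own term, 5274 with array weights, 1222 with blood cell scores as covariates and 0 on the second chip set, where limma gave 1259 at an unadjusted p under 0.05; the cause was not tested, except that the second set has 2 controls. Called lists numbered 17 and moved to 2 with neither batch term, 8 on the second chip set, 10 with blood cell scores as covariates, 4 with the interferon score as a covariate and 0 with an estimated correlation, where the interferon list, with its median of 1.23, had adjusted p = 0.0891. Lists and genes that themselves made up a covariate have no value there. With the replicate block, 32 controls and 32 Sjögren samples that share a number gave 8 called probes, 2249 at an unadjusted p under 0.05, from 64 arrays in place of all; 13 lists were called and the interferon score differed by 1.28. In the score test 5 of the 12 lists kept an adjusted p under 0.05 with the block, against 4 of 12 with neither batch term: the block gave adjusted p = 0.0832 for inflammatory cytokine, 0.141 for platelet, 0.180 for MHC class I, 0.315 for locus and for neutrophil, 0.372 for costimulation and 0.458 for proliferation genes. Further scores that passed with the block were -0.821 for T cell, 0.676 for immature granulocyte and -0.225 for immediate early genes, and with neither batch term -0.489 for T cell and -0.687 for globin genes. The shared numbers did not pair the samples: 11 of 32 pairs had a residual correlation over 0.1, with a median of -0.0187, and 0 controls correlated best with their own number. Signals below 0, 28.9% of all intensities, limit what dim probes can show. Without the probe filter 48796 probes were tested and 2274 called; the effects of low signal and of the larger number of tests were not separated.

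A direction counts as turned where a result past its threshold (unadjusted p for scores) changed sign, in the camera direction or the median for a list, or where one not past it passed with the opposite sign. This happened in 5 settings and in the second set with a control left out, and the cause was not tested beyond leaving out those controls. In 99 of 866 values past the threshold on neither side the sign also differed. With neither chip set nor chip in the model, list medians (log2) were -0.028 for MHC class I, -0.038 for monocyte and -0.089 for inflammatory cytokine genes, the inflammatory cytokine score was -0.00298 and the proteasome score -0.202, and log2 differences were -0.14 for TNPO3, -0.028 for PSMB8, -0.055 for MS4A7, 0.045 for PPBP, -0.019 for NFKBIZ and 0.054 for RPL21. On the second chip set alone, list medians (log2) were -0.0071 for MHC class II, 0.14 for neutrophil, -0.061 for monocyte, 0.76 for erythroid, -0.0036 for costimulation, -0.64 for proliferation and -0.19 for proteasome genes, and scores were -0.0902 for MHC class II, 0.323 for neutrophil, -0.197 for monocyte and -1.40 for proliferation genes. Log2 differences there were -0.040 for IFIT1, -0.14 for IFI6, 0.40 for TNIP1, -0.091 for PRDM1, -0.18 for PSMB8, 0.14 for CXCR1, -0.047 for FGL2, -0.23 for MS4A7, -0.39 for CD38, 0.15 for ESAM, 0.13 for STRADB, 0.94 for HEMGN, -0.36 for ATF3, 0.063 for PPP1R15A, 0.11 for FOSL2, -0.049 for CASP1, -0.030 for TNFSF13B, -0.43 for TOP2A, -0.77 for NUSAP1, -1.09 for TYMS and -1.09 for CCNA2. Single controls decided part of this: without control 13 those scores were -0.0986, 0.778, -0.219 and -3.29, and without control 14 they were -0.0818, -0.132, -0.176 and 0.488. Of the 21 genes 7, and of the 7 list medians 2, kept the turned sign whichever control was left out. With blood cell scores as covariates the MHC class II score was -0.0434. With the interferon score as a covariate, list medians were -0.023 for MHC class I, -0.011 for costimulation, 0.0042 for proliferation and 0.0031 for ribosomal protein genes, and log2 differences -0.20 for CD38 and -0.039 for TNFSF13B. With chip means removed, relations in the upper part were 0.0461 for oxidative phosphorylation, 0.322 for proteasome and 0.0147 for mitochondrial ribosomal protein genes.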

Other observations

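Tests chosen only after the result was seen were those on pairs of controls, on the share of high-scoring donors, on platelet genes and on age; every chip as its own term was a planned setting, used for platelet genes after its value was seen. The splits within chips were added after those within chip sets had been seen.

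Chance was tested with 100 splits of the arrays within chip sets, the real one included. The real split called 2858 probes and the highest of the others 63, so 1 of 100 splits gave as many and chance can be excluded for the number of genes. For gene lists with camera's preset correlation, the real split called 17 of 26 and 2 of 100 splits gave as many, which is under 5%; the highest other split also called 17, and the other 99 splits called a median of 9. Those splits ignored the chips, on which arrays resembled each other. With every chip as its own term and 100 splits within chips, which rest on the 21 control and 49 Sjögren arrays of the 16 chips with both groups, the real split called 1498 probes and the highest other 297, so 1 of 100 gave as many. It called 13 lists, the highest other split 15, and 12 of 100 gave as many, so chance cannot be excluded for the number of lists. Single lists therefore cannot be read from the preset p alone. Among the 100 splits within chip sets, at least as small a camera p came in 18 for platelet and 32 for neutrophil genes. It came in 57 for erythroid, 38 for ribosomal protein, 2 for type I interferon and 2 for locus genes. Such counts per list were not made for the splits within chips.

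The interferon difference was smaller on the second chip set, 0.639 against 1.81. Compressed signal there was argued against: the SD of Sjögren scores on the second set was 1.01 times that on the first (bootstrap 95% interval 0.888 to 1.14), whereas the ratio of the differences was 0.353. A smaller share of high-scoring donors may contribute, since 35.8% of Sjögren arrays of the second set lay above the boundary fitted in that set and 60% of the first (Fisher's exact p = 0.00134). The boundaries differed, at 2.17 and 1.41, and the test took them as fixed. Above the highest control of their own set lay 53.7% on the second and 41.1% on the first. Above the second highest lay 57.9% and 58.9%. By these measures, with 2 controls on the second set, a clearly smaller share was not seen. Whether the 2 controls of the second set were drawn high stays open: 4.37% of the 435 pairs of first-set controls gave a difference as small, with a bootstrap interval of 0 to 14.0 percent, added after the share was seen. If the Sjögren arrays of the 2 sets do differ in share, the alignment of the sets, which rests mostly on them, could shift the scores of the second set.

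Platelet genes were lower in Sjögren blood by a score difference of -0.519. With the number of detected probes as a covariate it was -0.417 (permutation p = 0.0188), with every chip as its own term -0.622 (permutation p = 0.00730) and with the interferon score as a covariate -0.476 (permutation p = 0.00860), so none of these trends accounts for it as the whole cause. As a hypothesis, Sjögren blood may hold a smaller share of platelet RNA; platelet counts and treatment were not used here, and handling of the tubes stays open.

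The falls of LRRN3 and CD248 raised the hypothesis of a difference in age between the groups, tested at the level of groups with genes recalled as lower or higher in blood of older people, LRRN3 and CD248 left out. The 14 measured genes lower with age had a score difference of -0.408 (permutation p = 0.0270), with 3 members shared with the T cell list, whose own score differed by -0.354; SLC16A10, FCGBP and EDAR, chosen after their values were seen, were the 3 that fell. The 17 genes higher with age, 8 of which are also in the cytotoxic list, had a score difference of 0.0327 (95% interval -0.306 to 0.371, permutation p = 0.848), so an age difference can be neither shown nor excluded. For 16 genes that glucocorticoids raise the score difference was -0.187 (95% interval -0.527 to 0.154, permutation p = 0.278), which leaves treatment open as well; MERTK, chosen after its values were seen, was the 1 member that rose.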
